A study of Mus musculus with 2 samples.

How the data were processed

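H3K9me3 chromatin immunoprecipitation and sequencing was done on embryonic mouse heart at day 13.5, with 2 biological replicates in 1 group, per the labels. Per the deposited record of each sample, the authors derived each replicate's peaks from its alignments and a control, with a different control file for each replicate. They derived a pooled list from both replicates, and a list of replicated peaks from the pooled list and both replicates' lists, on the assembly mm10. The aligner, the peak caller, its thresholds and the rule for a replicated peak are not given in the sources used here. The authors called peaks per replicate and on pooled replicates, so replicates were compared through their own lists. The deposited fold enrichment, −log10 p-value and −log10 q-value belong to the same peak. How the control entered the fold enrichment is not given in the sources used here. Peaks on different chromosomes often had the same fold, such as 6.03453 at Olfr212, Vmn1r73, Ddx4 and Myh8. A fold may therefore not be a ratio to the control at that peak. The lowest −log10 p was 2.02 in replicate 1, 2.03 in replicate 2 and in the pooled list. The deposited display score and summit offset were not used in any test, except that the summit gave each named peak its annotation. No list gives reads, so depth is unknown and no interval that needs it is given. An absent peak therefore means that none passed the authors' threshold.

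Peaks were compared with the GRCm38 genome and the GENCODE annotation M21 of the same build. The lists give no chromosome lengths, but every peak on the 21 chromosomes ended within its chromosome in that genome. Tests used the 21 chromosomes, and 251 replicated peaks on scaffolds were left out of them and counted apart. Analyses were written in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and Matplotlib 3.10.9. Overlap needed at least 1 bp. Expected values came from 1000 circular shifts of peaks within each chromosome after gaps were removed, which keep the widths and spacing of peaks. A two-sided permutation p was taken from the shifts, with 0.002 as the smallest possible value. Values over the 21 gene lists, and separately over the 4 annotation classes, were adjusted by Benjamini-Hochberg at a threshold of 0.05. Log2 ratios to expectation were taken after 0.5 was added to observed and expected members, or 0.01 to observed and expected percentages of bases. The background count over all protein-coding genes used 200 shifts.

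The main tests, the 21 gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The lists were Zfp genes, olfactory receptors, vomeronasal receptors, clustered protocadherins, Hox clusters, major urinary proteins, the Rhox cluster, histone genes, keratins, ribosomal proteins, imprinted loci, H3K9 methylation genes, housekeeping genes, germline genes, and markers of cardiomyocytes, endothelium and endocardium, epicardium with fibroblasts and smooth muscle, blood, neurons, hepatocytes and skeletal muscle. Gene windows were the gene span with 2 kb on each side, and promoter windows 1 kb on each side of any annotated start. Some genes belong to more than 1 list. Of the 31 symbols fixed for H3K9 methylation, 30 genes remained. Each base was put in the first class that held it, in the order promoter, exon, intron, intergenic. First and last exons came from the coding transcript with the longest coding sequence. Domains joined peaks at most 5 kb apart. The rule for named genes takes, in each list, the 4 members of highest fold enrichment that met a peak in both replicates, or every member with a peak where 5 or fewer had one. It also takes the 10 genes with most covered bases, the 10 peaks of highest fold enrichment and the 10 widest domains.

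The other settings fixed then were the pooled list, each replicate's own list, a −log10 q of at least 2, an overlap of at least 50%, peaks placed singly at random, other windows and merging at 1 kb. The 50% rule for gene windows was applied as the peak midpoint lying inside the window. Settings added after seeing the data were peaks met in both replicates, peaks of single-copy sequence, chromosomes without X and Y, covered bases in place of members, 500 bp windows at the start of the first exon and the end of the last, and shifts within uniquely mappable sequence. Copy number was the median genome count of the 31-base words in a peak. Mappable sequence was the set of 50 bp bins where at least 50% of 31-base words occurred once on the 21 chromosomes, by an approximate count, and amounted to 2126 Mb or 80.3% of assembled bases. The read length used by the authors is not given in the sources used here, so this is a guide to mappability only.

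The list test was tested on simulated data made by shifting the real replicated peaks, with 200 shifts in place of 1000 and so a smallest possible permutation p of 0.00995. In 30 simulated sets without an effect over 21 lists, 3.33% of p-values were under 0.05 and 0% of adjusted calls were made. With 200 shifts an adjusted call needed several lists at the smallest p together, which 1000 shifts do not need. The 0% therefore does not show the rate of false adjusted calls in the real test. Peaks were planted and removed in the same sets, so several lists could reach the smallest p at once there. Where peaks were planted in 60% of the windows of 5 lists, 77.3% of those lists were called. Lists emptied of peaks were called in 96.7% of sets for Zfp genes and for cardiomyocyte genes.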

Results

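The data were peak lists of trimethylated lysine 9 of histone H3 (H3K9me3), a histone mark of heterochromatin, from chromatin immunoprecipitation and sequencing of mouse embryonic heart at day 13.5. The 2 libraries were biological replicates of 1 group, made from pooled male and female embryos of the strain B6NCrl, so the only comparison between libraries was replicate against replicate. The labels give each library its own biosample and the same donor label. All other tests asked where in the genome the peaks lay. Their p-values concern placement in the genome and not the spread between animals. The authors' files held 73533 peaks for replicate 1 and 78272 for replicate 2 (mean 75902.5 ± 3351 SD, n = 2), with median widths of 247 bp and 242 bp. A list called on both replicates together held 127088 peaks, and the authors' list of replicated peaks held 44233. The replicated peaks had a median width of 454 bp, covered 24.3 Mb or 0.919% of the assembled sequence, and had a median fold enrichment of 3.58. Fold enrichment is the authors' own value for each peak throughout. The lists hold no read counts, so the depth of each library is unknown.

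The replicated list was not the same as the peaks found in both replicates. Each of the 44233 peaks was identical to a peak of the pooled list. Of the 43982 on chromosomes, 27537 (62.6%) met a peak of each replicate's own list by at least 50% of either peak. By an overlap of 1 bp, 15142 met a peak of exactly 1 replicate and 1017 met none. The median −log10 q was 5.05 for peaks met in both replicates, 3.41 for those met in 1 and 2.44 for those met in none. Here "replicated" means membership of the authors' list, and calls that end when only the 27537 peaks are used are given beside the result.

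The first comparison asked how far the replicates placed H3K9me3 at the same sites. Of the peaks of replicate 1 on chromosomes, 29900 of 73199 (40.8%) met a peak of replicate 2, and 38.5% of the peaks of replicate 2 met a peak of replicate 1. Circular shifts of one list along each chromosome gave means of 1.98% and 1.87%. The Jaccard index of covered bases was 0.200 against 0.00513 in shifts (two-sided permutation p = 0.002, the smallest that 1000 shifts can give). When each list was divided by q into 4 groups of equal size, the group with the strongest peaks met the other replicate in 62.2% of cases in replicate 1 and 60.1% in replicate 2. The group with the weakest peaks did so in 28.2% and 26.0%. Fold enrichment of the 28051 replicated peaks matched in both replicates, scaffolds included, was weakly related across peaks, with a Spearman rho of 0.240 and a Pearson r of 0.302 on the log2 scale. Only peaks called in both replicates entered, and fold enrichment had a narrow range, which can lower both values. Its 5th to 95th percentiles were 2.60 to 4.80 in the list of replicate 1 and 2.52 to 4.77 in that of replicate 2. Peaks are not independent replicates, so no p is given. The SD of the log2 ratio between replicates was 0.38.

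The next comparison asked which gene groups held replicated peaks, within the gene or 2 kb on each side. Among imprinted loci, 37 of 39 held a peak against 15.1 expected from shifts (adjusted permutation p = 0.0140, which follows from the smallest p the shifts can give). The count was 38 from the list of replicate 1 and 37 from that of replicate 2. Ndn and Dlk1 had none, and these 2 were chosen for naming after their values were seen. The highest values were at Impact, with a peak of 7.54-fold at chromosome 18:12972672-12974223 in an intron, and at Mest, with a 5484 bp peak of 7.14-fold at chromosome 6:30734981-30740464, also in an intron. A 7257 bp peak of 6.79-fold at chromosome 2:174294213-174301469 lay over Gnas, which encodes a G protein alpha subunit, and its antisense transcript Nespas. All coordinates are on mm10, and annotations of single peaks refer to the summit. The share of bases covered at imprinted loci was 3.86% against 1.42% expected, and at a log2 ratio of 1.44 against 1.27 for members this did not pass the test (adjusted permutation p = 0.155).

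Clustered protocadherins, a family of neuronal cell adhesion molecules encoded in tandem on chromosome 18, held a peak in 53 of 57 members against 26.5 expected (adjusted permutation p = 0.0168). The members without one were Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, chosen for naming after their values were seen. Each replicate's own list gave the same count, 53. Peaks covered 27.4% of the bases of these windows against 1.00% expected (adjusted permutation p = 0.0105). The strongest peak, 7.73-fold at chromosome 18:37722576-37723633, lay in introns of nested gene models that include Pcdhga1, Pcdhga2, Pcdhga3 and Pcdhgb1. It measured 6.07-fold in replicate 1 and 6.85-fold in replicate 2. Because these models overlap, 1 peak counts for several members.

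**Figure D1:**
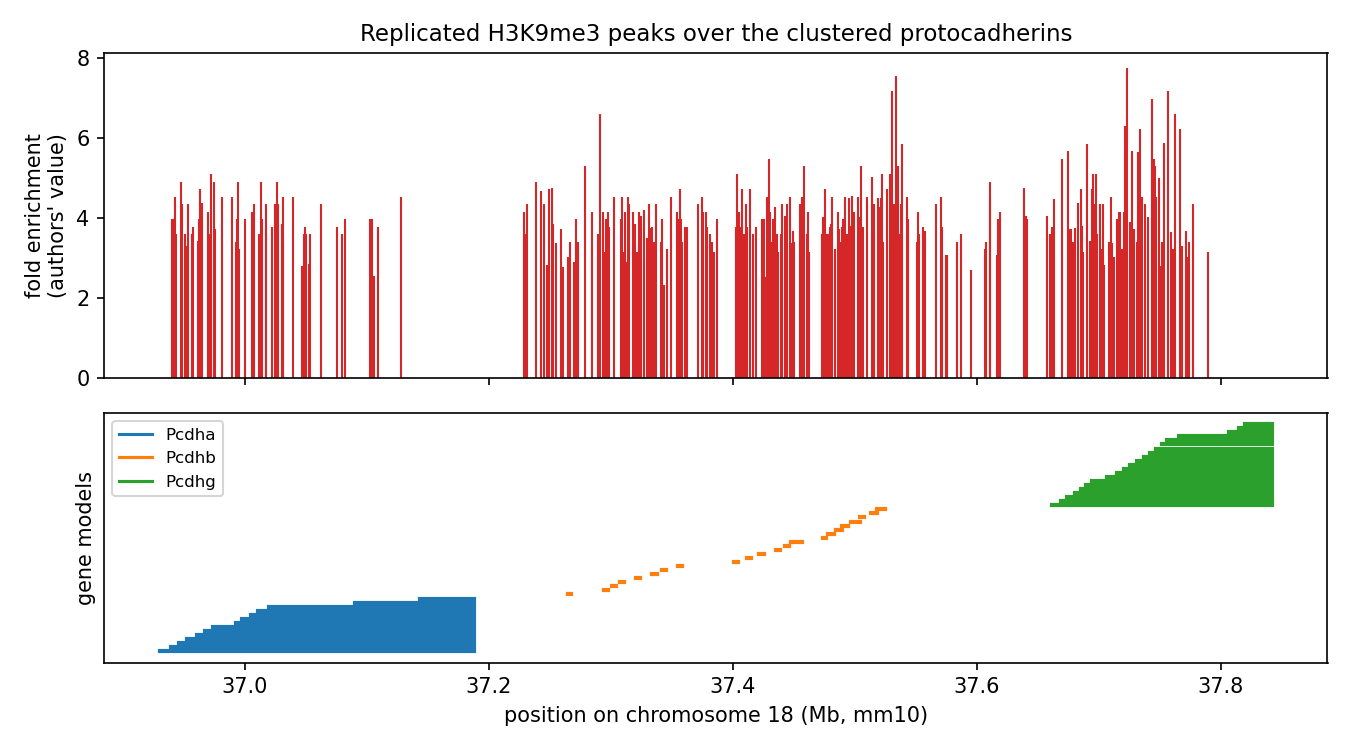
Replicated H3K9me3 peaks over the clustered protocadherins on chromosome 18 of mm10, with position in Mb on the x axis. Each red line is 1 peak at its midpoint with the authors' fold enrichment as its height, the lower panel draws each gene model from start to end by subfamily, and the highest line is the 7.73-fold peak in the Pcdhg subfamily.

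Zfp genes, most of which encode zinc finger proteins, held a peak in 186 of 391 members against 110 expected (adjusted permutation p = 0.0140). The highest values were at Zfp810, with a 12.3-fold peak at chromosome 9:22276307-22281096 in coding exon, Zfp777, with an 11.2-fold peak at chromosome 6:48023557-48026723 in the 3′ UTR, Zfp68, with a 10.7-fold peak at chromosome 5:138603787-138607916 in coding exon, and Zfp930, with a 10.2-fold peak at chromosome 8:69227765-69232556 in the 3′ UTR. Peaks covered 4.94% of the bases of Zfp windows against 1.20% expected (adjusted permutation p = 0.0105). The lists of replicates 1 and 2 gave 211 and 204 members. Against peaks placed singly at random, with a mean of 172 members, the count did not pass, and the log2 ratio to expectation, 0.75 against shifts, was 0.11 (adjusted permutation p = 0.207).

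Vomeronasal receptors, which detect pheromones, held a peak in 120 of 327 members against 74.6 expected (adjusted permutation p = 0.0280), with 5.11% of bases covered against 1.66% (adjusted permutation p = 0.0140). Each replicate's own list gave 139 members. Vmn1r73, Vmn2r58 and Vmn2r108 each had a peak of 6.03-fold, and Vmn2r112 one of 5.85-fold. Olfactory receptors held a peak in 232 of 1093 members against 148 expected (adjusted permutation p = 0.0300), with Olfr212 and Olfr943 at 6.03-fold, Olfr59 at 5.85-fold and Olfr380 at 5.66-fold. The lists of replicates 1 and 2 gave 332 and 350 olfactory members. Single random placement gave 129 vomeronasal and 219 olfactory members (adjusted permutation p = 0.422 for both), and the vomeronasal count then lay below expectation. The vomeronasal call, with a log2 ratio to expectation of 0.68, also ended without replicate 1, at 0.42 (adjusted permutation p = 0.0629), and with the pooled list, at 0.22 (adjusted permutation p = 0.165). The olfactory call, with a log2 ratio of 0.64, also ended for the gene span alone, at 0.36 (adjusted permutation p = 0.374). It ended at a higher log2 ratio for peaks met in both replicates, 0.72, for shifts within uniquely mappable sequence, 0.68, and for the share of bases covered, 0.66 (adjusted permutation p = 0.0755, 0.0539 and 0.300).

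Cardiomyocyte genes lay below expectation, with a peak in 4 of 30 members against 10.5 (adjusted permutation p = 0.0140). The 4 were Scn5a, a cardiac sodium channel, with 6.63-fold at chromosome 9:119507185-119508342, Cacna1c, a calcium channel subunit, with 4.76-fold at chromosome 6:118636758-118638327, Ttn, which encodes titin, with 3.57-fold at chromosome 2:76710571-76711196, and Ryr2, a calcium release channel, with 3.16-fold at chromosome 13:11765430-11765782. The Ttn peak was in coding exon and the others in introns, and this Ryr2 peak met no peak of replicate 1. The lists of replicates 1 and 2 gave 7 and 6 members. Members without a replicated peak included Nppa, Myh6, Myh7, Tnnt2, Actc1, Nkx2-5, Gata4 and Tbx5. With only peaks met in both replicates the same number of members, 4, stood against 8.34 expected, a log2 ratio of −0.97 where all replicated peaks gave −1.29 (adjusted permutation p = 0.132), and the share of bases covered was 0.402% against 0.927% (adjusted permutation p = 0.214). Ribosomal protein genes held a peak in 1 of 79 members, Rpl3, with a 3.58-fold intronic peak at chromosome 15:80086467-80086853, against 8.92 expected (adjusted permutation p = 0.0168). The lists of replicates 1 and 2 gave 3 and 2 members. That call, with a log2 ratio of −2.65, ended with peaks met in both replicates, at −2.17 (adjusted permutation p = 0.0979), and with the gene span alone, at −2.001 (adjusted permutation p = 0.0959).

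The other lists did not pass for whole genes. No member of the Hox clusters, which hold developmental regulators, had a peak among 39, against 4.88 expected (adjusted permutation p = 0.155). That list passed below expectation without replicate 2 (adjusted permutation p = 0.0420) and against random placement (adjusted permutation p = 0.0233). The 16 blood genes, with the globins among them, had none against 3.18 expected (adjusted permutation p = 0.117), and passed below expectation without replicate 1 (adjusted permutation p = 0.0240), without replicate 2 (adjusted permutation p = 0.0280), with the pooled list (adjusted permutation p = 0.0180) and against random placement (adjusted permutation p = 0.00699). The 22 major urinary protein genes had none against 2.65 (adjusted permutation p = 0.402), and passed below expectation only against random placement (adjusted permutation p = 0.0462). Of 28 housekeeping genes 1 had a peak, Gusb, at 3.55-fold, against 5.52 (adjusted permutation p = 0.117, but 0.0458 without replicate 2, 0.0373 with the pooled list and 0.0120 against random placement, all below expectation), and the lists of replicates 1 and 2 gave 2 and 3. Genes of H3K9 methylation and its readers had 9 of 30 against 11.7 (adjusted permutation p = 0.484, and below expectation 0.0300 without replicate 2 and 0.00699 against random placement), with Smchd1 at 8.11-fold, Fam208a at 5.48-fold, Atf7ip at 4.91-fold and Kdm4c, a histone demethylase, at 4.53-fold.

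Among the other cell types of the heart, endothelial and endocardial genes had 8 of 16 against 7.20 (adjusted permutation p = 0.913), with Npr3 at 5.47-fold, Tek, an angiopoietin receptor, at 4.90-fold, Flt1, a receptor of vascular endothelial growth factor, at 4.35-fold and Erg at 4.29-fold. Epicardial, fibroblast and smooth muscle genes had 3 of 18 against 5.39 (adjusted permutation p = 0.465), namely Myh11, a smooth muscle myosin, at 4.34-fold, Pdgfrb at 4.02-fold and Aldh1a2 at 3.96-fold, and the lists of replicates 1 and 2 gave 4 and 6 members. Neuronal genes had 8 of 24 against 10.96 (adjusted permutation p = 0.347, and 0.0233 below expectation against random placement), with Slc17a7, a vesicular glutamate transporter, at 9.49-fold, Syt1 at 7.73-fold, Gad1 at 4.90-fold and Cntnap2 at 4.53-fold, a peak that met no peak of replicate 2. Their share of bases covered was 0.183% against 1.46% and passed below expectation (adjusted permutation p = 0.0105). Hepatocyte genes had 5 of 18 against 4.35 (adjusted permutation p = 0.913), namely Cyp3a11 at 4.71-fold, Cyp2c29 at 4.53-fold, Ambp at 4.34-fold, Cps1 at 3.58-fold in a peak that met no peak of replicate 2, and Trf, which encodes transferrin, at 3.39-fold. Their share of bases covered was 4.62% against 0.932% and passed above expectation (adjusted permutation p = 0.0105), with 24 peaks in the window of Cyp3a11 and 16 in that of Cyp2c29, both members of tandem cytochrome P450 families. Skeletal muscle genes had 6 of 20 against 5.24 (adjusted permutation p = 0.913), with Myh8 at 6.03-fold, Cacna1s and Ryr1 at 4.53-fold and Pax7 at 3.96-fold.

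Of the remaining gene families, the Rhox cluster of homeobox genes on chromosome X had 1 of 34, Rhox13 at 6.79-fold, against 1.71 (adjusted permutation p = 1). Histone genes had 2 of 67 against 5.18 (adjusted permutation p = 0.679), Hist1h2ba and Hist1h2aa, which shared a 2.83-fold peak that met no peak of replicate 2. Keratins had 2 of 49 against 5.85 (adjusted permutation p = 0.420), Krt8 at 4.15-fold and Krt32 at 3.58-fold, and the lists of replicates 1 and 2 gave 5 and 2. With the pooled list keratins passed below expectation, with 2 members against 13.4 (adjusted permutation p = 0.00839). Among all 21938 protein-coding genes, 23.4% held a peak against 28.9% expected (permutation p = 0.00995, the smallest that 200 shifts can give).

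**Figure D2:**
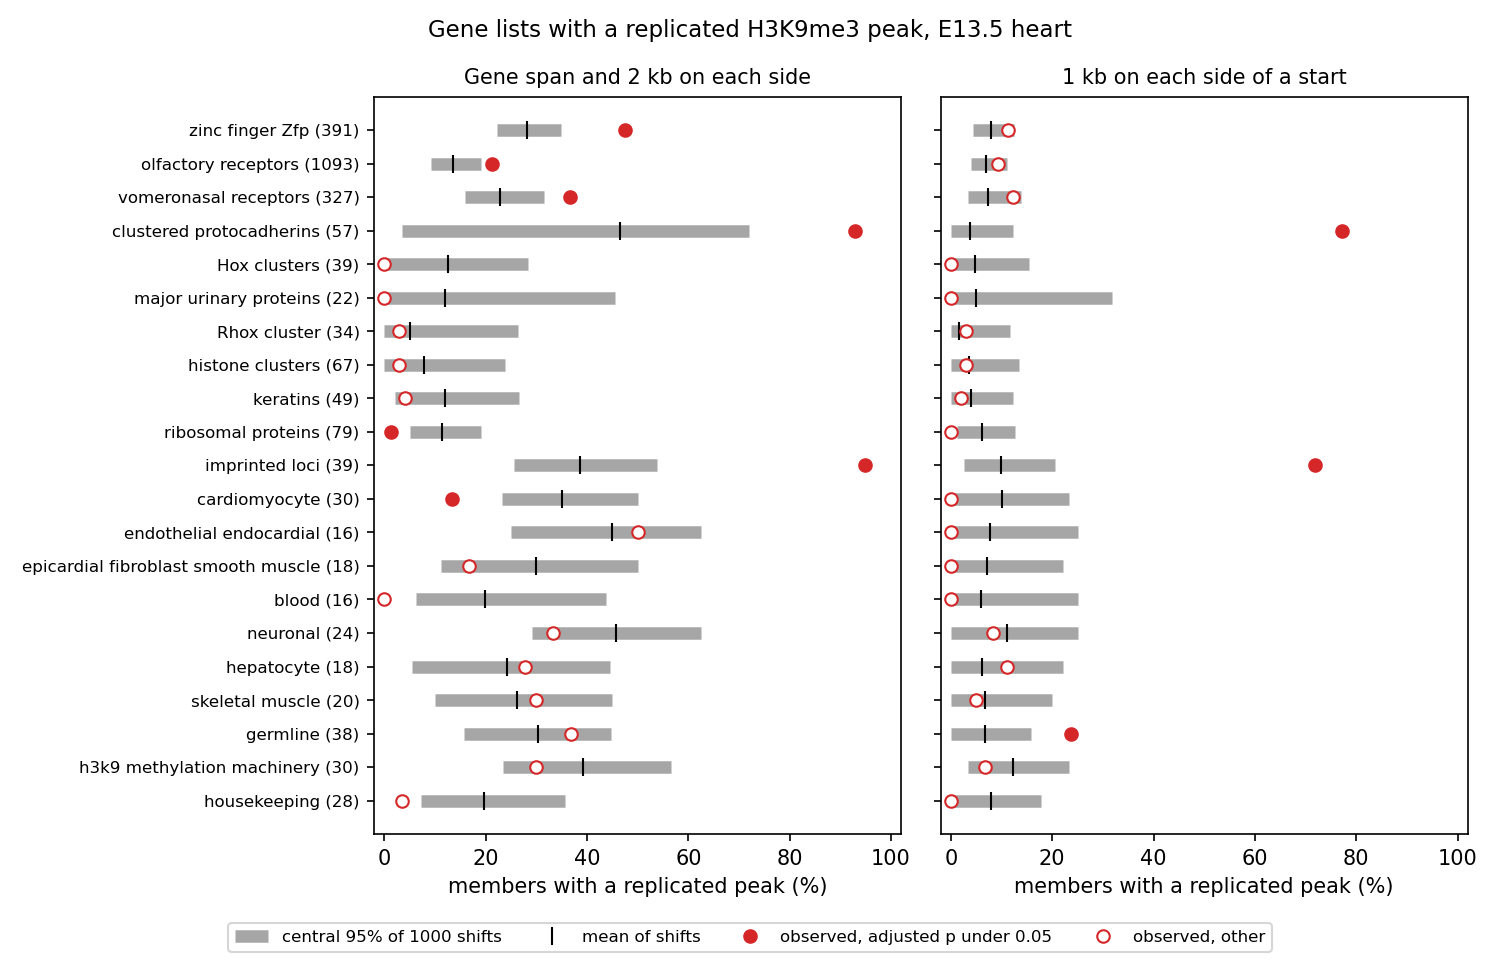
Share of each fixed gene list with a replicated peak, as a percentage of members on the x axis, for gene windows (left) and promoter windows (right), with the number of members in parentheses. Grey bars span the central 95% of 1000 circular shifts, ticks are their mean, filled circles have an adjusted permutation p under 0.05, and imprinted loci reach 94.9% and clustered protocadherins 93.0% on the left.

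At promoters, within 1 kb of an annotated transcription start, 3 of the 21 lists lay above expectation and none below. Clustered protocadherins had 44 of 57 members with a peak against 2.18 expected, imprinted loci 28 of 39 against 3.87, and germline genes 9 of 38 against 2.54 (adjusted permutation p = 0.0140 for each). The germline members were Mael, Sycp2, Sycp1, Fkbp6, Stag3, Ddx4, Dmc1, Dazl and Taf7l, several of which act in meiosis. Ddx4, a germ cell RNA helicase, had a 6.03-fold peak at chromosome 13:112651624-112652679, and Dazl, a germ cell RNA-binding protein, a 5.85-fold peak at chromosome 17:50293094-50294505. Tdrd9 at 5.09-fold and Prdm9 at 4.51-fold had peaks inside the gene but not at the promoter. Fkbp6 belonged to both the imprinted and the germline list. Over whole genes, germline members had 14 of 38 against 11.5 expected and did not pass (adjusted permutation p = 0.580). No promoter had a peak among cardiomyocyte genes, against 3.03 expected, or ribosomal protein genes, against 4.89 (adjusted permutation p = 0.394 and 0.136). With the pooled list both passed below expectation, at 0 cardiomyocyte promoters against 6.50 and 2 ribosomal against 10.9 (adjusted permutation p = 0.00839 for each), as did housekeeping genes, at 0 against 4.85 (adjusted permutation p = 0.0360). The ribosomal list also passed below expectation without replicate 1, against random placement and with windows of 2 kb (adjusted permutation p = 0.0210, 0.0280 and 0.0210). Zfp genes had 44 promoters with a peak against 30.9, vomeronasal receptors 40 against 24.2 and olfactory receptors 101 against 75.3 (adjusted permutation p = 0.480, 0.480 and 0.564). The lists of replicates 1 and 2 gave 50 and 53 Zfp, 54 and 62 vomeronasal and 160 and 166 olfactory promoters, and with the pooled list the olfactory receptors passed above expectation, with 246 promoters against 163 (adjusted permutation p = 0.0360). Of all protein-coding genes 4.09% had a promoter peak against 7.42% expected (permutation p = 0.00995, the smallest that 200 shifts can give).

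Within Zfp genes replicated peaks were found more often in the last exon, which usually encodes the zinc finger array, than in the first. Of 390 Zfp genes with several exons, 137 (35.1%) had a replicated peak in the last exon and 6 in the first. In 132 genes only the last exon had one and in 1 gene only the first (exact two-sided sign test, p = 2.46e-38, a description because the genes are clustered). Peaks covered 21.6% of last-exon bases and 0.439% of first-exon bases. Last exons are longer, with a median of 2492 bp against 143 bp, and shifts gave 22.9 last exons (permutation p = 0.002) and 7.004 first exons (permutation p = 1). A further count used windows of 500 bp at the end of the last exon and at the start of the first. The start window reached past first exons shorter than 500 bp, so it was not limited to the exon. In these windows 90 genes had a peak in the last alone and 1 in the first alone. In 20136 other protein-coding genes, 476 last exons had a peak against 651 in shifts and 205 first exons against 296 (permutation p = 0.002 for each), and 397 genes had a peak in the last alone against 126 in the first alone (exact two-sided sign test, p = 1.11e-33, also a description). Among these other genes peaks covered 1.06% of last-exon bases and 1.62% of first-exon bases. With the 500 bp windows 209 genes had a peak in the last alone and 151 in the first alone (exact two-sided sign test, p = 0.00261). Here the start window met a peak in 225 genes, more than the 205 with one in the whole first exon.

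**Figure D3:**
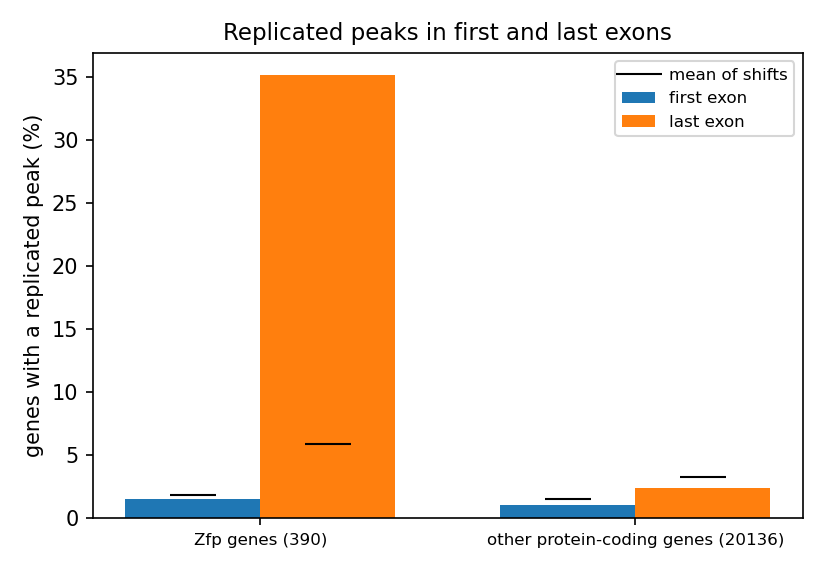
Percentage of genes with a replicated peak in the first exon and in the last exon, for 390 Zfp genes and 20136 other protein-coding genes with several exons. Bars are observed shares, black lines are the means of 1000 shifts, and the last exon of Zfp genes reaches 35.1%.

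By annotation, 59.6% of replicated peak bases were intergenic against 49.96% in shifts, 29.6% were intronic against 40.0%, and 4.34% were exonic against 3.49% (adjusted permutation p = 0.00266 for each). Promoter bases made up 6.48% against 6.57% and did not pass (adjusted permutation p = 0.755), but passed below expectation without replicate 2, at 5.996% (adjusted permutation p = 0.03996), and with the pooled list. With the pooled list the exonic share lay below expectation without passing, at 3.41% against 3.44%. Soft-masked repeats made up 36.3% of peak bases against 33.9% in shifts (permutation p = 0.002). Their share of all assembled bases was 36.4%, so the excess was over shifts within each chromosome and not over the genome share.

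Chromosome 7 carried the most replicated peaks, 39.8 per Mb, followed by chromosome 17 with 31.9. The median autosome had 16.0 and the lowest, chromosome 14, had 10.9. Chromosome X had 6.19 per Mb, or 0.345 times the autosomal density, and chromosome Y 0.193. Of assembled bases outside gaps, 84.0% of autosomal sequence, 68.4% of X and 3.46% of Y was uniquely mappable by 31-base words. Per mappable Mb, the densities were 21.4 on autosomes, 9.05 on X and 5.58 on Y. The replicates differed on X, with 1814 peaks in replicate 1 and 3323 in replicate 2. That ratio, 1.83, lay outside the autosomal range of 1.01 to 1.08. Chromosome Y had 65 and 26 peaks. The ratio of X to autosomal density was 0.373 from replicate 1 alone and 0.653 from replicate 2 alone.

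**Figure D4:**
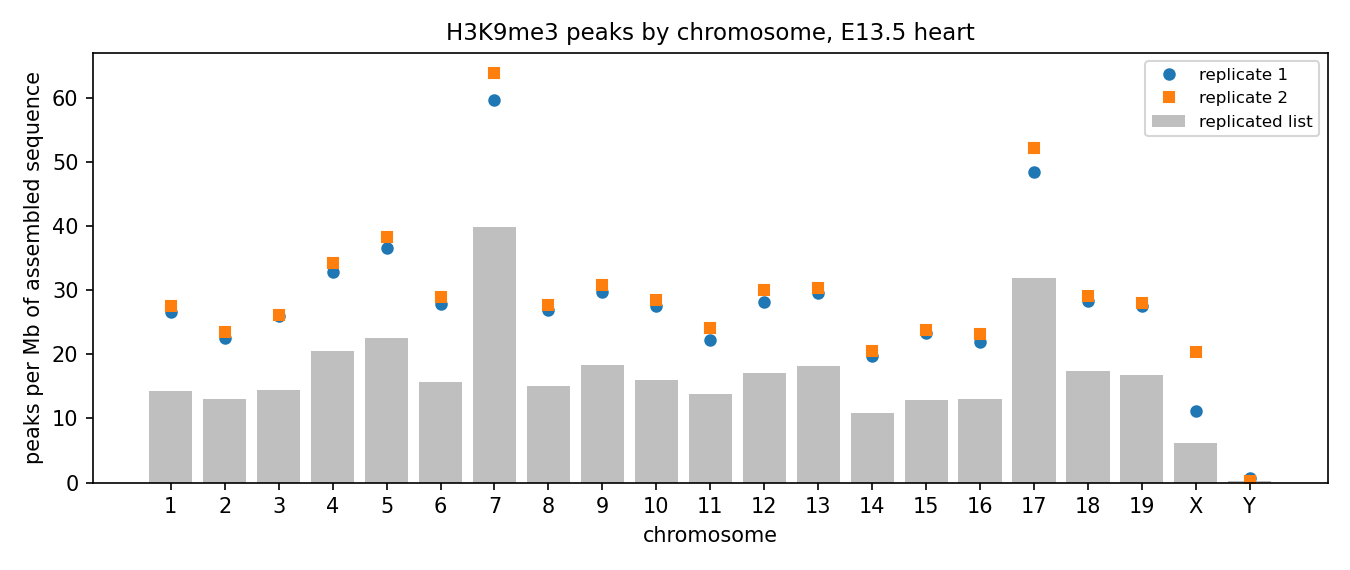
Peaks per Mb of assembled sequence (y axis) on each chromosome (x axis). Grey bars are the replicated list, circles replicate 1 and squares replicate 2, chromosome 7 is highest at 39.8 replicated peaks per Mb, and X has 1814 peaks in replicate 1 and 3323 in replicate 2.

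Replicated peaks at most 5 kb apart formed 26638 domains, of which 478 held at least 5 kb of covered bases and 132 of those lay on chromosome 7. The widest by covered bases, at chromosome 7:17932747-18107742, held 112 peaks and 85153 covered bp over Ceacam11, Ceacam12 and Ceacam13. The second, at chromosome 18:37656720-37777783, covered 67157 bp of the Pcdhg genes. The third, at chromosome 7:23339241-23477791, covered 57910 bp over Nlrp4e and Nlrp5. The fourth, at chromosome 1:88210173-88257917, covered 44915 bp over the Ugt1a genes, which encode glucuronosyltransferases, and Mroh2a. The others among the 10 widest lay near Gm12892 and Gm12887 on chromosome 4, over Scgb pseudogenes on chromosome 7, at the start of the assembled chromosome 3, over BC024063 and AU041133 on chromosome 10, and over Pcdhb15 to Pcdhb22 on chromosome 18. Among single genes, the readthrough models Gm42416, Gm37013 and Gm37388 over the protocadherins had the most covered bases, up to 214851 bp. Skint5 had 72208 bp and Skint6 67745 bp covered, and the long non-coding RNA C230088H06Rik 57757 bp.

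The replicated peak of highest fold enrichment, 18.48, lay at chromosome Y:258992-259547 in intergenic sequence whose 31-base words occur 2 times in the genome. It measured 17.6-fold in replicate 1 and 17.5-fold in replicate 2. Next was a 13.8-fold peak in coding exon of Klf14, a transcription factor gene, at chromosome 6:30955397-30958716. A peak that reached into Tcfl5 from an intergenic summit at chromosome 2:180642564-180644774 and one in introns of Gm49329 and Gm49331 at chromosome 12:17903634-17904199 both had 11.7-fold, and one in coding exon of Asmt, which encodes an enzyme of melatonin synthesis, at chromosome X:170674194-170678080 had 10.96-fold. An intergenic peak at chromosome 5:104582143-104582830, 27935 bp from D930016D06Rik, had 10.8-fold. A peak on an unlocalised scaffold of chromosome 4 had 12.7-fold, with 4.90-fold in replicate 1 and 13.9-fold in replicate 2. Zfp810, Zfp777 and Zfp68, described above, complete the 10.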

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

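The test of a deeper replicate 2 and the filter on single-copy sequence were chosen after the data were seen, as was the condition that both replicates match X peaks evenly. On scaffolds outside the 21 chromosomes, which the comparisons of genes and chromosomes leave out, there were 251 replicated peaks on 22 scaffolds. They stand here because they are signal in data that the comparisons do not use. Replicate 1 had 334 scaffold peaks and replicate 2 had 356, and the median fold enrichment of the replicated ones was 4.15 against 3.58 on chromosomes.

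Replicate 2 had more chromosome X peaks than replicate 1, with a count ratio of 1.83. A deeper or more sensitive replicate 2 would raise peaks of equal strength on the autosomes alike. Pooled peaks were put in 8 groups of −log10 q after ties were merged. The share met by replicate 2 over that met by replicate 1 was 1.88 on X and at most 1.17 on an autosome at the same strengths. The bootstrap SD of 0.0567 on X came from resampling single X peaks 200 times. It treats peaks as independent and does not measure the spread between libraries. These values argue against greater depth or sensitivity as the whole cause. The ratio of peak counts in the replicates' own lists, by contrast, was 2.26 on X against 1.20 on autosomes at a −log10 q of at least 2. This count ratio was 1.55 against 1.65 at 5 and 0.905 against 1.36 at 10, where X had 21 and 19 peaks. Another dosage of X and Y in the pools or their controls cannot be told apart from other causes: the median log2 fold of matched X peaks, replicate 2 over replicate 1, was −0.0229, inside the autosomal range, which by the prediction written before would have excluded it. That exclusion was not drawn. Replicated X peaks met replicate 1 in 59.3% and replicate 2 in 81.7% of cases, so the matched peaks left out many X peaks. Whether a dosage shared with the control would move fold depends on how the control entered it, which is not given in the sources used here. No biological explanation was tested.

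Peaks in clustered gene families may reflect reads shared between near-identical copies. With only peaks of single-copy sequence, the lowest ratio to expectation among Zfp, olfactory, vomeronasal and protocadherin genes was 1.57, and the 4 lists passed. That filter took out only 619 of 43982 peaks, and Zfp members with a peak went from 186 to 184, so it could hardly change the 4 calls. Multi-copy sequence made up 5.46% of the 788 peaks in Zfp windows, above the 1.39% of all replicated peaks on chromosomes. It made up 0.649% in olfactory, 0.152% in vomeronasal and 0.429% in protocadherin windows. These low shares argue against identical 31-base words in several copies as the whole cause. Copies that differ within most 31-base words count as single-copy, so reads shared between such copies were not tested. Copies missing from the assembly would look single-copy here and stay open. No biological explanation was tested.

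The peaks of highest fold enrichment may lie in collapsed or multi-copy sequence in the assembly. Multi-copy sequence made up 4% of the top 100 peaks against 1.38% of the others (permutation p = 0.104, 100000 resamples). The share was higher without passing, so with 100 peaks an excess of multi-copy sequence cannot be told apart from chance. Copies collapsed in the assembly would look single-copy here, so this count cannot speak to collapsed sequence at any number of peaks. The highest peak of all, on chromosome Y, was in sequence of 2 copies. No biological explanation was tested.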

How the results depend on the processing

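Peaks met in both replicates, single-copy peaks, covered bases, 500 bp exon ends, autosomes alone and mappable shifts were chosen after seeing the data. Replicate overlap and the preference of Zfp peaks for the last exon kept direction and side of the threshold under every alternative run for them. So did the soft-masked excess over shifts. Of 504 values for single gene lists under alternatives, 467 kept their side of the threshold, 13 lost the call, 23 gained one and 1 reversed. The reversal was of the vomeronasal receptors with random placement, with a log2 ratio of −0.10. A change of direction counted as a reversal only where the main or the other value passed. Among the 467, some lists that passed in neither setting changed direction. Hepatocyte genes, for example, had a log2 ratio of 0.18 in the main setting and −0.57 without replicate 1. In no case below was the cause tested, except that random placement spreads clustered peaks over more genes by its construction. Depth is unknown and limits which weak peaks could be called. No paired analysis was possible because there is 1 group.

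The number of lists above expectation, 5, became 2 with random placement and 4 with the pooled list, without replicate 1, with the gene span alone, with peaks met in both replicates, with mappable shifts and with covered bases, where hepatocyte genes entered and imprinted loci and olfactory receptors left. The number below, 2, became 5 with the pooled list, 8 with random placement, 1 with the gene span alone and 0 with peaks met in both replicates, and ranged from 3 to 6 when 1 replicate was left out; with covered bases it was 2, with neuronal in place of cardiomyocyte genes. At promoters the number above, 3, became 4 with the pooled list, and the number below, 0, became 3 with the pooled list, 1 with random placement and 1 with windows of 2 kb, and ranged from 0 to 1 when 1 replicate was left out. The promoter share was 5.63% with the pooled list, where it passed below expectation, ranged from 5.996% to 6.05% when 1 replicate was left out, and was 7.01%, now above expectation without passing, with peaks met in both replicates. The exon share with the pooled list, 3.41%, lay below its expectation of 3.44%. The density of X over autosomes was 0.582 with the pooled list, 0.254 with peaks met in both replicates and 0.424 per mappable Mb. It ranged from 0.373 to 0.653 when 1 replicate was left out. For chromosome 7 it was 1.90 with the pooled list, 2.28 with peaks met in both replicates, 2.40 per mappable Mb, and ranged from 2.00 to 2.05 when 1 replicate was left out. The rho of fold enrichment was 0.201 with the widest overlapping peak and 0.227 at a −log10 q of at least 2. Domains of at least 5 kb numbered 818 with the pooled list and 220 with merging at 1 kb.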

Other observations

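The tandem families were chosen after the widest domains were seen, the count of families able to pass was added after their result, the reading of the repeat test in both directions and the shifts within mappable sequence were chosen after their results or the data were seen, and GC and CpG content were described without a prediction. Among 18 further tandem gene families, Klra genes, which encode natural killer cell receptors, held a replicated peak in 8 of 11 members against 2.53 expected, and Obox genes, which encode homeobox proteins, in 6 of 7 against 2.43. Cyp3a genes, of the cytochrome P450 family, had 6 of 7 against 2.45, Cyp2 genes 21 of 48 against 13.4, and Tas2r bitter taste receptors 7 of 35 against 2.30. Prl genes, of the prolactin family, had 0 of 25 against 3.79, and Ifna and Taar genes had none. The hypothesis that tandem arrays in general hold more members with a replicated peak than expected was not borne out: 0 of the 18 families passed after adjustment, where the prediction against it, written before, was fewer than 5. Without adjustment 2 passed above expectation, Klra (permutation p = 0.0360) and Obox (permutation p = 0.0440), and both had an adjusted permutation p of 0.306. With a peak in every member, 18 of 18 families would pass after adjustment if all were filled together, and 13 if each was filled alone with the others as observed. More members than expected held a peak in 9 of the 18. An excess too small to pass in single families was not excluded.

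Replicated peaks were nearly absent from highly repeated sequence. The hypothesis was that their share in sequence of 10 or more copies equals that of chance placement, and the prediction against it named an excess. The share was 0.148%, far below the 7.93% to 9.17% of 10 shifted placements of 10000 peaks. Placement by chance over all assembled sequence was thus excluded, in the direction opposite to the one written before the result. The placements also covered sequence that is not uniquely mappable, so the test cannot speak to placement among sites where peaks could be called. The files alone cannot show whether multi-mapping reads were removed before peak calling, which is a candidate explanation. Within mappable sequence, soft-masked repeats made up 32.5% of peak bases against 23.5% in shifts (permutation p = 0.002), a wider gap than over all assembled bases. The median GC content of peaks was 44.3% against 41.6% to 42.2% in the shifted placements, while CpG sites numbered 0.592 per 100 bp against 0.617 to 0.666. Both were compared with the placements over all assembled sequence and not within mappable sequence. These gaps therefore cannot be told apart from an effect of mappability.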
